A study of Mus musculus with 8 samples.

How the data were processed

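RNA was measured by mRNA sequencing in mouse mammary epithelial cells of the FVB strain, which the labels name PyVmT and in which Uba7 had been knocked out. Uba7 encodes UBE1L, the enzyme that activates the ubiquitin-like protein ISG15 for attachment to other proteins (ISGylation). The labels describe 8 libraries in 4 groups of 2. The cells carried either an empty vector or UBE1L, every library title names IFN, and in 2 of the groups LPS was added at 100 ng/mL for 6 hours. The type, dose and duration of IFN are not given in the sources used here. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values may measure only technical spread.

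Per the labels' protocols, stranded poly-A libraries were made from RNA with integrity numbers of 9.2 to 10.0, and single reads of 50 bases were sequenced. Trimmomatic 0.36, Salmon 0.9.1 and edgeR are named, with no role or order, in the submitters' processing notes. The genome build, annotation, count filter and model are not given in the sources used here. Salmon divides reads among transcripts by estimation, so genes with near-identical copies are less certain.

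The values used come from a single table of 259 genes, which per the file headers compares UBE1L with control cells under IFN and LPS. The header of the fold column names the UBE1L cells OE, read here as overexpression. No group with intact Uba7 is described, so the UBE1L level cannot be set against a normal one. It holds 5 columns of results per gene and no values per library. As deposited by the authors, the fold change is a log2 value of UBE1L over empty vector. The mean abundance, as deposited by the authors, is a log2 CPM (counts scaled to library size) over libraries that the file headers do not name. The base of both logarithms is not named there and was taken as 2, as edgeR writes columns of these names in the authors' table. The likelihood-ratio score and its unadjusted p-value were used as deposited, and the p-value equals the upper tail of a chi-square with 1 degree of freedom at that score to within a relative difference of 6.60e-13. The adjusted p-value was also used as deposited by the authors, and its header names both Bonferroni and FDR. The depth of each library is unknown from this table, so no counting interval is given, and the table holds no standard error or standard deviation. An approximate standard error, derived from the fold and the likelihood ratio, stands only in the closing observations.

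Because the table holds the authors' own comparison, no test across libraries was run. As planned for a table of this kind, genes were counted by direction, and members of 18 gene lists (330 genes) fixed before the data were examined were looked up by exact symbol. Named genes are the ISGylation machinery, the 8 largest rises and 8 largest falls, and up to 4 listed members of each list with the largest absolute fold, 45 genes in all. Oasl1, Cxcl10 and Il15 fall outside this rule and were named, after their values were seen, to complete lists with 5 listed members. The rule's uncalled members could not be named, since the table lists only genes past its limits. Adjustment over a list alone needs the p-values of its other members and was not possible. The effect of UBE1L without LPS, the effects of LPS, their interaction and the overlap between comparisons need other values and were not analysed here.

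Sequence shared between genes was found by taking every stretch of 50 bases in the GENCODE M21 transcripts of each listed gene. Those that also occur in a transcript of another gene on the same strand were counted. All 259 symbols had transcripts there, 1 of them under another symbol. A gene with 20% or more shared stretches is described as uncertain. The count does not separate similar copies from annotated genes that overlap at the same place. The search recovered the known share in simulated sequences. Since no build is named for the table, coordinates are not printed, and the RefSeq gene table (GRCm38.p6) served only for synonyms and for the order of genes.

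Ranks of the listed genes among all genes tested were computed from the ratio of adjusted to unadjusted p-value, and the procedure recovered every rank in 5 of 5 simulated tables. Those tables were built with the formula that the procedure inverts. They check the computation only and say nothing on which adjustment the authors used. Bounds on chance listing used the hypergeometric distribution, with every list member taken as tested and the number of tests taken as 6414, the constant that links p, rank and adjusted p rounded up. That this constant does not exceed the number of tests is an assumption, since the ranks alone show 2342 tests. The plan allowed only counts of list members for a table of selected genes, so these bounds were added after seeing the data and stand in the closing observations. Directions of neighbouring genes were tested with 100000 shuffles of the directions. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives were an adjusted p under 0.01, absolute log2 folds of at least 1 and 2, and matching of symbols by synonyms. A Bonferroni adjustment, leaving out uncertain genes, a minimum abundance and a subtracted offset were chosen after seeing the data.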

Results

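The data compare mRNA levels in Uba7-knockout mouse mammary epithelial cells with added UBE1L or an empty vector, all exposed to IFN and LPS. UBE1L is the ISG15-activating enzyme encoded by Uba7. The labels do not say whether several lines were made with each vector. Other differences between the UBE1L and the empty-vector cells therefore cannot be told apart from an effect of UBE1L. LPS is a bacterial outer membrane lipid sensed by Toll-like receptor 4, and IFN stands for interferon, whose target genes include Isg15 itself. The comparison sets 2 UBE1L libraries against 2 empty-vector libraries, all with IFN and with LPS at 100 ng/mL for 6 hours. The authors' deposited table lists 259 genes for this comparison, of which 217 (83.8%) were higher and 42 were lower with UBE1L. A scaling offset of 0.277 log2 units would make the upper and lower tails of these folds hold equally many genes, Uba7 left out. It was set from these same genes after seeing the data, takes the excess of rises as not real and measures no scaling error. With this offset subtracted, 90 of these genes would stay higher past the same fold limit and at least 42 would be lower. The p limit was not applied again after the subtraction. The smallest absolute log2 fold change in the authors' deposited table is 0.50 and the largest adjusted p is 0.0498, so every listed gene had passed both limits. A gene that is not listed was either not tested, below the fold limit or not past the p threshold, and is not counted as unchanged. Mean abundance in the authors' deposited table ran from -0.49 to 9.58 log2 CPM, with a median of 2.95.

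Uba7 changed most among the listed genes. Its transcript was 52.7-fold higher in the UBE1L cells (log2 fold change 5.72), at a mean abundance of 9.58 log2 CPM, and both its p and its adjusted p stand as 0 in the authors' deposited table. This direction is the one the library labels give, since both kinds of cell are labelled Uba7 knockout and UBE1L was added to 1 of them; values per library were not analysed here. The other 5 members of the ISGylation machinery list were Isg15, Ube2l6 (the ISG15 conjugating enzyme), Usp18 (the ISG15 protease), Herc6 and Trim25. None of these 5 is listed in the authors' deposited table.

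Median changes were under 1 log2 unit. In the authors' deposited table the median log2 fold was 0.72 among the higher genes, a 1.65-fold difference, and -0.62 among the lower genes. At least 1 log2 unit separated the cells for 51 higher and 8 lower genes in the authors' deposited table. After Uba7, the largest listed rises were in Fmod (fibromodulin, a collagen-binding proteoglycan), at 2.38 log2 units with an adjusted p of 2.44e-06, and Glcci1 (a glucocorticoid-induced transcript), at 2.11 with an adjusted p of 1.68e-15, both by the edgeR values in the authors' deposited table. Ndrg2 followed at 1.92, Sema3b (a secreted semaphorin) at 1.73, Fcrlb (adjusted p 0.0105) at 1.63, the protocadherin Pcdhga1 (adjusted p 0.0222) at 1.60 and the nucleoside transporter Slc28a3 at 1.56 in the authors' deposited table. Mean abundance there was 0.81 log2 CPM for Fmod, -0.07 for Ndrg2, -0.11 for Fcrlb and 0.39 for Pcdhga1. It was 1.65 for Slc28a3, 1.67 for Sema3b and 2.73 for Glcci1. Glcci1 and Pcdhga1 are uncertain, because 69.9% and 39.0% of their 50-base stretches also occur in other genes.

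The largest listed fall was in Prl2c3, a proliferin of the prolactin family, which was 3.89-fold lower with UBE1L (log2 fold change -1.96, adjusted p 1.23e-13) in the authors' deposited table. Of its 1357 stretches, 814 also occur in its relative Prl2c2, so its value is uncertain. The authors' deposited table gives smaller falls for Zfp708 at -1.60, the transcript EU599041 at -1.59, the chemokine gene Cxcl12 at -1.31, Zfp991 at -1.21 and the neurotrophin receptor gene Ngfr at -1.19. The Ly49 receptor genes Klra1 at -1.20 and Klra4 at -1.16, also fell in the authors' deposited table. The zinc finger genes Zfp708 and Zfp991 share 94.9% and 82.2% of their stretches with other genes. Among these 8 genes the mean abundance exceeded 1 log2 CPM only for Prl2c3, at 3.35, and Klra4, at 2.84, in the authors' deposited table.

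**Figure D1:**
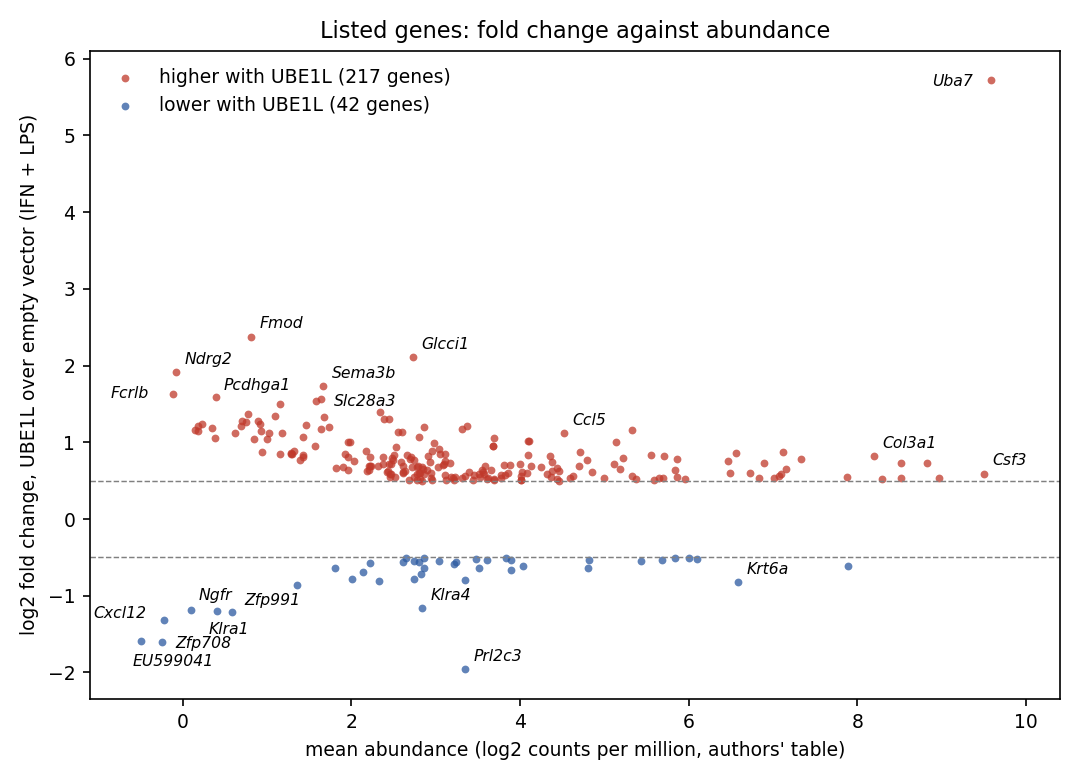
Each point is 1 of the 259 genes in the authors' deposited table, with mean abundance in log2 CPM on the x axis and the log2 fold change of UBE1L over empty vector under IFN and LPS on the y axis. The 217 higher genes are red and the 42 lower genes are blue, dashed lines mark 0.5 and -0.5, and Uba7 stands alone at 5.72.

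The listed interferon-stimulated genes were higher with UBE1L, as were most listed genes. Of 42 targets of interferon fixed in advance, 5 rose and 0 fell in the authors' deposited table, and the other 37 are not listed there. The 5 were Ifit1bl1 (1.01, adjusted p 0.00361), the RNA-binding antiviral gene Ifit2 (0.78, adjusted p 2.73e-40), Phf11d (0.77, adjusted p 5.12e-13), the antiviral GTPase gene Mx1 (0.66, adjusted p 1.48e-20) and Oasl1 (0.52, adjusted p 4.80e-13), each as a log2 fold from the authors' deposited table. Of these 5, Ifit1bl1 and Ifit2 would stay past the fold limit with the scaling offset of 0.277 log2 units subtracted. Guanylate-binding proteins and immunity-related GTPases act on intracellular pathogens, and 4 of 17 rose with 0 falling in the authors' deposited table. They were Gbp5 at 0.85, Gbp8 at 0.63, Tgtp1 at 0.59 and Iigp1 at 0.54 log2 units in the authors' deposited table, and with the offset subtracted 1 of the 4, Gbp5, would stay past the fold limit. Tgtp1 shares 81.2% of its stretches with other genes, and 79.4% of all its stretches occur in its near-copy Tgtp2.

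Antigen presentation and chemokine genes were also among those that rose. Nlrc5, a transcriptional activator of MHC class I genes, was 1.84-fold higher (log2 fold change 0.88, adjusted p 6.78e-19), and the immunoproteasome subunit gene Psmb9 was 1.65-fold higher (0.72, adjusted p 7.67e-13), in the authors' deposited table. They were the 2 listed members of a list of 26, of which Nlrc5 would stay past the limit with the offset subtracted. Among 21 chemokine genes, 4 rose and 1 fell in the authors' deposited table. Ccl5 rose by 1.12 log2 units, Cxcl11 by 1.07, Cxcl9 by 0.59 and Cxcl10 by 0.53 in the authors' deposited table, with adjusted p of 3.92e-17, 1.69e-06, 0.0320 and 2.07e-12. Ccl5 and these CXCR3 ligands attract T cells. Of the 4, Ccl5 and Cxcl11 would stay past the limit with the offset subtracted. The 1 chemokine that fell was Cxcl12, at -1.31 log2 units with an adjusted p of 0.0408 and a mean abundance of -0.22 log2 CPM in the authors' deposited table.

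The NF-kB and LPS response list had 5 of 41 members higher and 0 lower in the authors' deposited table. The cytokine gene Il1a rose by 1.12 log2 units (adjusted p 0.0229), Il6 by 0.72 (adjusted p 0.00763), Tnfaip2 by 0.64 (adjusted p 5.93e-12), the granulocyte growth factor gene Csf3 by 0.59 (adjusted p 8.26e-14) and Il15 by 0.51 (adjusted p 0.0110) in the authors' deposited table. With the offset subtracted 1 of these 5, Il1a, would stay past the limit. Il1a had the lowest mean abundance of the 5, at 0.62 log2 CPM, and the highest adjusted p, so its fold is the least certain. Csf3 was the second most abundant listed gene after Uba7, at 9.50 log2 CPM in the authors' deposited table. From the unfolded protein and heat-shock list of 15, 3 members rose and 1 fell in the authors' deposited table. The rises were in Ddit3 (a stress-induced transcription factor) at 0.70, Trib3 at 0.57 and Herpud1 at 0.51 log2 units, while the heat-shock gene Hspa1a fell by 0.66 on the log2 scale, in the authors' deposited table. None of these 3 rises would stay past the limit with the offset subtracted. Hspa1a shares 60.3% of its stretches with other genes, mainly its copy Hspa1b.

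**Figure D2:**
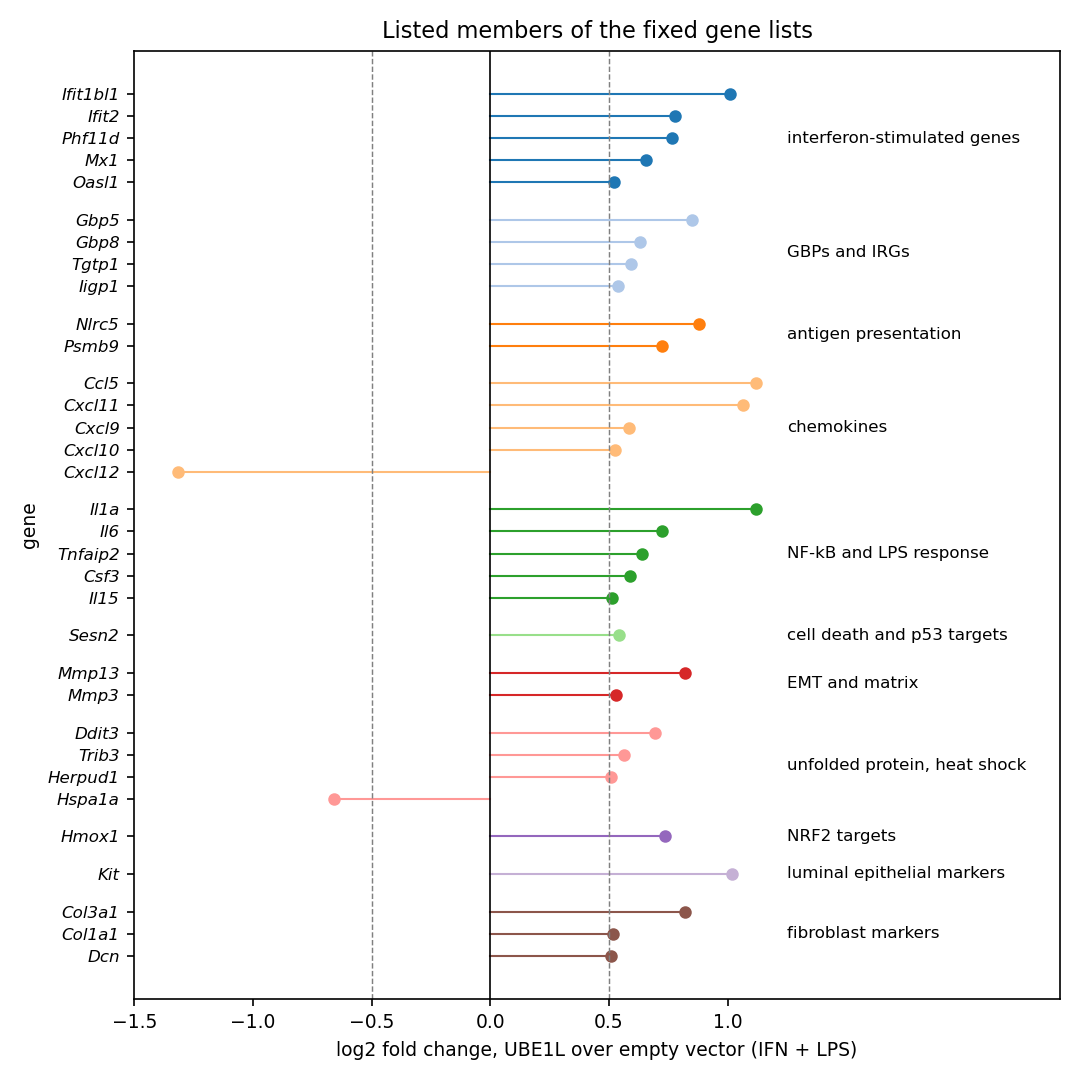
The x axis gives the log2 fold change of UBE1L over empty vector under IFN and LPS, and each row is a gene of a list fixed in advance that the authors' deposited table contains, Uba7 left out. Points right of 0 were higher with UBE1L; Cxcl12 at -1.31 and Hspa1a at -0.66 lie to the left.

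The listed members of the fibroblast marker list were higher with UBE1L. Of 9 fibroblast markers, the collagen genes Col3a1 (0.82, adjusted p 1.95e-37) and Col1a1 (0.52, adjusted p 2.64e-09) and the proteoglycan gene Dcn (0.51, adjusted p 0.000460) rose in the authors' deposited table, and 0 fell. The matrix protease genes Mmp13 at 0.82 and Mmp3 at 0.53 log2 units were the 2 listed members of 23 on the epithelial-mesenchymal list in the authors' deposited table. Kit, the stem cell factor receptor gene, rose by 1.02 log2 units (adjusted p 5.77e-17) and was the 1 listed member of 15 luminal markers in the authors' deposited table. Single members were listed for NRF2 targets, with 1 of 10 and the heme oxygenase gene Hmox1 at 0.74, and for cell death and p53 targets, with 1 of 17 and Sesn2 at 0.54, in the authors' deposited table. No member of 6 lists appears in the authors' deposited table: cell cycle (21 genes), hypoxia and glycolysis (14), basal and myoepithelial markers (12), macrophage and leukocyte markers (18), endothelial and adipocyte markers (8), and ligands and checkpoints of T and NK cells (15).

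Across the 18 lists, the authors' deposited table held 34 members, 32 higher and 2 lower, and 225 of its genes belonged to no list. All p-values come from the authors' likelihood-ratio test on groups labelled with 2 libraries each, and the spread between those libraries was not analysed here. At an absolute log2 fold of at least 1, 7 list members passed. With the scaling offset subtracted 11 of the 32 higher ones would stay past the fold limit. Among the 11 were Col3a1, Mmp13 and Kit but not Col1a1, Dcn, Mmp3, Hmox1 or Sesn2. Uba7, added by design, is counted in the 34, the 32, the 7 and the 11.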

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

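The stricter settings on folds and the level of the p threshold were chosen before the data were examined; the Bonferroni, shared-stretch, abundance and offset settings were chosen after. With an adjusted p under 0.01, 177 genes remained (153 higher, 24 lower), and the 34 list members became 29. At an absolute log2 fold of at least 1 there were 59 genes and 7 list members, and at 2 there were 3 genes, all higher (100%), of which 1, Uba7, was a list member. Bonferroni over 6414 tests left 104 genes, 88.5% of them higher, and over 2342, the number of tests the ranks show, 113. A mean abundance of at least 4 log2 CPM left 74 genes, with 22 list members. Leaving out genes with 20% or more shared stretches gave 229 genes (198 higher, 31 lower). Subtracting the offset that balances the tails left 90 of the 217 higher genes and 11 of the 32 higher list members, Uba7 included in both. Genes that would join the lower side are not listed. Matching symbols by synonyms gave the same 34 list members. Of the 45 named genes, 35 passed at an adjusted p under 0.01, 28 with Bonferroni and 21 at a fold of at least 1. Except for the offset, these settings select among deposited values and cannot reverse a direction; with the offset subtracted every listed higher gene also stays above 0, since the smallest rise is 0.50. The lower counts follow from the settings' construction.

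No paired analysis was possible because the table holds no values per library. For the same reason the planned fits with other scaling, filters, pseudocounts, libraries or left-out replicates, and all settings for the other comparisons, were not run. Depth per library is unknown and its effect on the calls was not measurable.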

Other observations

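The shared-stretch tests and the test of all neighbouring pairs were set before their results were seen; the tests of weak expression, Uba7 reads, scaling, chance listing, leukocyte markers and unrelated neighbours, and the genes in the next 2 paragraphs, were chosen after.

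Several small gene families had every listed member higher with UBE1L in the authors' deposited table, in which 83.8% of all genes are higher. They were 3 Phf11 genes (log2 folds of 0.77 to 1.37, the lowest being Phf11d, already counted among the interferon-stimulated genes), 3 Trim30 genes (0.72 to 1.31), 3 Schlafen genes (0.55 to 1.20), 3 Ly6 genes (0.73 to 0.86), 2 Sectm1 genes (0.78 and 1.20) and the speckled protein genes Sp110 (1.13) and Sp140 (1.14), all by the authors' deposited table. With the scaling offset of 0.277 subtracted, 2 members each of the Phf11, Trim30, Schlafen, Ly6, Sectm1 and speckled protein genes would stay past the fold limit. Phf11a, Phf11b, Sp110, Sp140 and Ly6c1 share 32.8% to 47.0% of their stretches with other genes and are uncertain. Single genes that rose in the authors' deposited table were Hp (haptoglobin) by 1.40, Cfb (complement factor B) by 1.01, Acod1 (the itaconate-producing enzyme) by 0.87, Ltf (lactotransferrin) by 0.76 and Lbp (LPS-binding protein) by 0.59 log2 units. Of these 5 genes, Ltf and Lbp would not stay past the limit with the offset subtracted. Cfb shares 73.0% of its stretches with the annotated gene Gm20547. Ly6c1 had the lowest p after Uba7, at an edgeR adjusted p of 1.47e-45 in the authors' deposited table.

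Solute carrier genes numbered 8 (0.50 to 1.56) and collagen genes 4 (0.52 to 1.05, with Col3a1 and Col1a1 already counted as fibroblast markers), all higher, in the authors' deposited table, and 5 of the 8 and 2 of the 4 would stay past the limit with the offset subtracted. Of 6 Zfp zinc finger genes 4 were lower in the authors' deposited table, but all 4 are uncertain, with 32.1% (Zfp442) to 94.9% (Zfp708) of their stretches shared, and the 2 higher ones are not. The most abundant lower genes in the authors' deposited table were the ribosomal protein gene Rpl27 (-0.61, edgeR adjusted p 1.79e-23), the keratin gene Krt6a (-0.82, adjusted p 1.05e-30) and Prrg4 (-0.52). Matrix genes among the lower ones in the authors' deposited table were Pcolce2 (an enhancer of procollagen processing) at -0.80 and the hyaluronan synthase gene Has2 at -0.54. Krt6a shares 45.7% of its stretches with other genes, mainly Krt6b, and Rpl27 shares 23.5%. Of the 259 genes, 30 had 20% or more shared stretches, 19 among the 217 higher and 11 among the 42 lower genes.

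The adjusted p-values of the authors' deposited table carry information on genes that it does not list. Each equals p times 6413.48 divided by a whole number, to within 4.35e-10 of a whole number, and these whole numbers act as ranks. Bonferroni would give 1 ratio for every gene and Benjamini-Hochberg a whole number of tests, so the column follows neither. It is also not monotone, since the adjusted p falls as p rises at 7 steps between listed genes, for example from Ltf (9.00e-28) to Hmox1 (8.13e-28), which a q-value would not do. The adjustment behind it was not identified here, and the number of tests is known only to be at least 2342, the highest rank. Of these ranks, 2083 belong to genes not among the rows used here, and the 259 genes are 11.1% of those ranked. The 27 genes with the lowest p are listed, as are 40 of the first 50, 56 of the first 100 and 158 of the first 1000. A limit on fold change would leave such genes out, but their folds are not known here.

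The first pattern is the excess of higher genes. Without genes that share stretches, 86.4% of 228 genes other than Uba7 were higher (exact 95% interval 81.3% to 90.6%). At 4 or more log2 CPM 86.3% of 73 were (76.2% to 93.2%). These shares argue against shared sequence or weak expression as the whole cause. Both intervals take genes as independent and do not measure the spread between libraries or cultures. Were the mean abundance taken over 8 libraries and all Uba7 reads in the 2 UBE1L libraries with LPS, Uba7 would hold 0.306% of their reads on average, a shift of the scale by 0.00443 log2 units, against the 0.277 that would balance the tails. An offset in library scaling stays open. After subtracting 0.277 log2 units, with Uba7 left out, 42 higher and 42 lower genes lie beyond 0.78 by construction. Then 14 and 14 lie beyond 1.03 and 7 and 8 beyond 1.28, while at the limit of 0.5 the lower side is incomplete. These tails cannot decide for an offset, because they pair rises from 1.05 with falls from 0.5 and the p limit acted before subtraction. The 57 genes under 2 log2 CPM, 49 higher and 8 lower, had a median approximate standard error of 0.38. At that error a fall near 0.5 would hardly pass the p limit. A true excess of rises in the UBE1L cells also stays open, and the folds of all tested genes would be needed to separate it from an offset. Even those folds would not tell an effect of UBE1L from other differences between the cells or cultures.

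The second pattern is the number of interferon and LPS response genes among the listed genes. The interferon-stimulated, GTPase, antigen presentation, chemokine and NF-kB lists hold 147 genes, of which 21 are listed. If 6414 genes were tested, 5.91 would be listed by chance (one-sided exact hypergeometric p = 3.32e-07, genes taken as independent and not matched on abundance). With 2342 tests the value would be 0.123 (one-sided exact hypergeometric p = 0.123), and 2611 or more are needed for one under 0.05. The gene at rank 2342, N4bp2l1, has an unadjusted p of 0.0182 by the authors' likelihood-ratio test. With 2342 tests no tested gene would have a higher one, and with fewer than 2611 only a small part would. That argues against so few tests, and so against chance listing of independent genes as the whole cause. A shift that these genes share, or their abundance, stays open as a reason for the count. Of the 34 members of all 18 lists, Uba7 included, 22 were among the 74 genes with at least 4 log2 CPM. The ranks are inferred, however, and the number of tests was not identified. Of the 21, 20 are not among the genes that share stretches, a count that argues against shared sequence as the whole cause. Without the sharing genes the exact hypergeometric p was 1.86e-07 on the first assumption. Stretches were counted only for listed genes, so unlisted genes with copies stayed in this value and it adds little to the count. With 6414 tests, the hypergeometric p adjusted over 18 lists was 0.0203 for the GTPase, chemokine, unfolded protein and fibroblast lists and 0.0767 for the interferon-stimulated and NF-kB lists. The other lists were at 0.607 or more, among them antigen presentation at 0.633, with 2 of 26 listed against 1.05 by chance. These values of single lists were not computed for fewer tests, so they rest on the assumption of 6414. Leukocytes in the culture cannot be told apart from a response of the epithelial cells, since 0 of 18 leukocyte markers are listed and a marker not listed excludes nothing, while leukocyte genes outside that list, picked after their values were seen, go both ways in the authors' deposited table (Mpeg1 at 0.89, Klra1 at -1.20 and Klra4 at -1.16); the UBE1L difference that the design names also stays open.

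The third pattern, a hypothesis, is that neighbouring genes changed together. Among listed genes within 3 protein-coding genes of each other, 29 of 29 pairs share a direction, against 21.4 expected when directions are shuffled (one-sided permutation p = 0.000500), and many of these pairs are related genes such as Phf11a and Phf11b. Pairs of unrelated genes were defined in 2 ways: the definition tried first, symbols that differ in their first 4 letters, gave 15 of 15 pairs alike against 11.1 expected (one-sided permutation p = 0.0110). It was replaced after that result was seen, because it kept relatives such as Sp110 with Sp140 and Mmp13 with Mmp3; with symbols that differ in their first 2 letters and known relatives left out, 9 of 9 pairs were alike against 6.63 expected (one-sided permutation p = 0.0607). Each p is the smallest its number of pairs allows, so the second test could not have passed 0.05 and decides nothing, and 1 of its 9 pairs, Ifi47 with Olfr56, shares stretches; common ancestry and shared position cannot be told apart.

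The fold divided by the square root of the likelihood ratio approximates the standard error of each log2 fold in the authors' deposited table. Its median was 0.38 in 57 genes under 2 log2 CPM and 0.07 in 24 genes at 6 or more, Uba7 left out. These medians cover only genes that passed both limits of the table and do not describe other genes.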
